A study of Brassica napus with 45 samples.

How the data were processed

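RNA was sequenced from leaves of Brassica napus seedlings grown in nutrient solution at 25 °C with 16 h of light and 8 h of darkness, per the labels' protocols. Total RNA was extracted with TRIzol, mRNA was isolated and libraries were made with the NEBNext Ultra II kit, per the labels' protocols. The 45 libraries formed 15 groups of 3, named by genotype and treatment in the sample titles. The knockout experiment held 18 libraries (wild type and a BnNAC038 knockout line) and the overexpression experiment held 27 (its own wild type and lines 1 and 2), each in untreated leaves, after 50 µM ABA for 3 h and after 20% PEG for 6 h, with the times taken from the column names. The wild type columns of the knockout experiment carry a different name from those of the overexpression experiment, so each mutant was compared only with the wild type of its own experiment. For overexpression line 2 the genotype field of the labels names a series of differently numbered NAC genes, 1 per library, while the titles name BnNAC038 throughout. The titles were followed. The titles call the libraries biological replicates without saying whether each came from separate plants or pools, so p-values measure only the spread between these libraries.

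The authors deposited a single file with a separate block of columns for each experiment. The values of the overexpression experiment were deposited per transcript and are TPM, as read from the values, because every library had the same sum over the 107233 listed transcripts, that of TPM. They were summed here to 100919 genes, of which 4109 had more than 1 transcript. The knockout experiment was deposited by the authors as another normalized value per gene (78057 genes), with no statement whether it is TPM or FPKM, and with library sums of 760713 to 842688. This block lists no gene at 0 in all of its libraries. Per the submitters' processing notes, HISAT2, DESeq2 1.38.3, kallisto 0.51.1 and sleuth 0.30.1 were used, with no role or order given. The genome build and annotation are not given in the sources used here. Because the blocks were normalized separately, every test was made within one experiment, and levels are never compared between the experiments. Neither block holds read numbers, so the depth per library is unknown and no counting interval is given. Brassica napus carries related A and C subgenomes, and reads shared between near-identical gene copies may have been divided between them by the authors' counting, which is a limit on any single copy's value.

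The identifiers carry a chromosome (A01 to A10, C01 to C09 in this species) and a number that runs along it, and these were used for gene order. Positions below are that running number, without the identifier's final zeros, and not base coordinates. The table does not pair identifiers with names, and the identifiers matched 0 of the 123214 genes of the reference table at hand, which is from the Da-Ae assembly. Gene names are therefore not given, and the BnNAC038 gene itself and the 40 gene lists fixed beforehand were not analysed here.

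Tests were made in R 4.3.3 with limma 3.58.1, and tables were read with data.table (version 1.17.8). The plan had foreseen a test for counts if the file held counts, and limma for normalized values. The unit required limma. Values were transformed as log2(value + 1), genes with a value of at least 1 in at least 3 libraries of the experiment were tested (42926 and 47474 genes), and a linear model over all groups of an experiment was fitted with empirical Bayes moderation and a mean trend, with no replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The 19 comparisons were ABA and PEG against untreated in each wild type, the knockout and each overexpression line against its own wild type in each condition, and the interaction that asks whether a treatment response differed between a mutant and wild type. These comparisons, their model, the threshold and the settings varied first (listed last below) were chosen before the data were examined. With no names, the planned rule gave at most 2 identifiers per direction and comparison: the largest changes among called genes with at least a 2-fold change, a mean of at least 5 in the higher group and replicate values that do not overlap (for the overexpression lines, genes called alike in both lines), and genes called in opposite directions in the knockout and in both lines. No identifier was taken for the interactions. The model was tested on simulated values with 100 genes changed by 1 and 100 by 2 on the log2 scale. It recovered 71% and 98% of them for ABA in the knockout experiment's wild type, 80% and 99% for the untreated knockout against wild type, 42% and 94% for the ABA interaction of the knockout, 86% and 99% for untreated line 1 against wild type, and 52% and 93% for the PEG interaction of line 1, with 2.12% to 5.79% false calls.

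Overlaps of calls were set against the number expected for independent lists (the product of both list lengths over the genes tested in both) with Fisher's exact test, two-sided. Where comparisons share control libraries, 50 simulations of unchanged groups gave the correlation, covariance and overlap that shared controls produce when genes vary independently. Responses of the mutants to each treatment were described beside the interactions. Chosen after seeing the data were the following. Chromosome segments were runs in which windows of 30 consecutive tested genes held at least 10 calls of one direction with a fold of at least 1.5, and 100 shuffles of the gene order counted how often such a run arises. Treatment-responsive gene sets were genes called with at least a 2-fold change in the wild type of one experiment, tested in the other experiment with camera (preset inter-gene correlation 0.01, and estimated correlation) and fry, over 48 tests. Each comparison was also repeated on equal splits of its own libraries (all 10 for a pair of groups, and for an interaction the real one and 99 drawn at random), with the bound written down after the real counts were known and before the splits were run. For the interactions this was done again after the genotype effect (mutant minus wild type, averaged over both treatments) had been subtracted per gene from the mutant libraries. Genotype marker genes were at most 0.1 in all untreated and PEG-treated libraries of one side and at least 3 in those of the other side, the sides being the wild type and the overexpression lines.

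The settings varied as set out beforehand were quantile normalization, no mean trend, no filter, a filter of at least 5 in at least 3 libraries, a pseudocount of 0.1, a required 2-fold change, a replicate block, a fit with only the compared groups, each overexpression line alone in the overlap with the knockout, and each library left out in turn. Settings added after seeing the data were array quality weights, knockout values rescaled to equal library sums, the first transcript of each gene only, all segments left out, and the libraries that stand apart left out (untreated wild type replicate 3 and PEG-treated knockout replicate 3, and ABA-treated wild type replicates 2 and 3 of the overexpression experiment). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.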

Results

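Leaf transcriptomes of Brassica napus (rapeseed) were compared between wild type, a knockout of BnNAC038 and 2 lines that overexpress it. BnNAC038 belongs to the NAC family of plant transcription factors, and the series addressed its part in the balance of drought response and growth. Leaves came from untreated seedlings, from seedlings given 50 µM abscisic acid (ABA), a hormone of water stress, for 3 h, and from seedlings given 20% polyethylene glycol (PEG), which lowers the water potential around the roots, for 6 h. The 45 libraries fell into 15 groups of 3, with 18 libraries in the knockout experiment and 27 in the overexpression experiment, each with its own wild type. The values were normalized by the authors, so read depth is unknown. Between 33267 and 39156 genes had a value of at least 1 per library in the knockout experiment, and between 38105 and 41754 in the overexpression experiment. Libraries of one group correlated across genes at 0.971 or more in the first and at 0.978 or more in the second, and no pair of columns was identical. The gene identifiers could not be paired with names, so the target gene in each library was not analysed here and genes are given by identifier.

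ABA changed a large part of the wild type leaf transcriptome. In the knockout experiment 21185 of 42926 tested genes changed after 3 h (limma, adjusted p under 0.05), 5464 higher and 15721 lower, and 6227 of them by at least 2-fold. In the overexpression experiment 16463 of 47474 genes changed, 7778 higher and 8685 lower, and 4523 by at least 2-fold. In the first, BnaA03G0537200ZS went from 0.186 ± 0.170 (SD, n = 3) to 160.3 ± 25.4, a log2 change of 7.09 (SE 0.34, limma adjusted p = 2.13e-09), and BnaC09G0580800ZS from 0.236 ± 0.166 to 128 ± 21.6. BnaC03G0338500ZS dropped from 80.2 ± 54.2 to 0.803 ± 0.396, a log2 change of -5.28 (SE 0.48, limma adjusted p = 6.37e-07). In the second, BnaC05G0064400ZS went from 2.84 ± 0.789 TPM to 573 ± 127.0 TPM (log2 change 7.22, SE 0.30, limma adjusted p = 3.58e-14) and BnaA01G0002500ZS from 89.1 ± 13.03 TPM to 0.859 ± 0.355 TPM (log2 change -5.60, SE 0.36, limma adjusted p = 4.21e-11). The surplus of lower calls in the knockout experiment depended on the normalization. Quantile normalization moved the median change of all tested genes from -0.23 to -0.01 and gave 8208 higher and 8978 lower. It makes the distributions of all libraries alike, so it cannot tell an effect of scaling from a true surplus. With values rescaled to equal library sums, 5749 genes were higher and 15542 lower. Without ABA-treated wild type replicates 2 and 3 of the overexpression experiment, in which genes otherwise absent from wild type were present, 10435 genes were called, 5476 higher and 4959 lower.

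PEG changed more genes than ABA in both experiments. After 6 h, 25633 genes differed from untreated wild type in the knockout experiment, 14372 higher and 11261 lower, and 29501 in the overexpression experiment, 18886 higher and 10615 lower. Of these, 9072 and 10017 changed by at least 2-fold. The most strongly raised gene was the same in both. BnaC02G0556300ZS went from 0.135 ± 0.0807 to 1018 ± 307 (SD, n = 3) in the knockout experiment (log2 change 9.76, SE 0.56, limma adjusted p = 5.12e-09) and from 0.0610 ± 0.106 TPM to 2290.3 ± 984 TPM in the overexpression experiment (log2 change 10.97, SE 0.31, limma adjusted p = 4.11e-17). It was also the gene most raised by ABA in the overexpression experiment, at 191 ± 74.5 TPM (log2 change 7.42, SE 0.31). BnaA07G0334400ZS went from 170.0 ± 53.9 to 1.42 ± 1.58 in the knockout experiment (log2 change -6.27, SE 0.45) and BnaC09G0459300ZS from 264 ± 28.9 TPM to 4.14 ± 2.66 TPM in the overexpression experiment (log2 change -5.86, SE 0.42). The surplus of higher calls in the overexpression experiment depended on the normalization. Quantile normalization moved the median change of all tested genes from 0.20 to 0.01 and gave 14078 higher and 14204 lower. Because it makes library distributions alike, it cannot tell an effect of scaling from a true surplus. ABA-treated and PEG-treated leaves were harvested after different times, so the counts do not rank the treatments at a matched time.

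The separate wild types responded to each treatment with largely overlapping genes. Of 39236 genes tested in both experiments, 3623 were raised and 5513 lowered by ABA in both, where 937 and 2735 would be expected of independent lists. PEG raised 10971 and lowered 6309 in both, where 5859 and 2336 would be expected. Opposite calls were fewer than expected, with 48 and 449 genes for ABA and 175 and 760 for PEG. Fold changes correlated across genes at r = 0.690 for ABA and 0.742 for PEG (Spearman 0.637 and 0.724), and genes are not independent replicates. Without the libraries that stand apart, ABA-treated wild type replicates 2 and 3 of the overexpression experiment among them, ABA raised 3047 and lowered 3123 genes in both. These comparisons share no library.

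ABA and PEG also moved many of the same genes. In the knockout experiment 4235 genes were raised and 8404 lowered by both treatments, and in the overexpression experiment 6152 and 5271. Genes raised by ABA and lowered by PEG numbered 237 and 294, and genes lowered by ABA and raised by PEG numbered 1154 and 533. Independent lists would share 1829 raised and 4124 lowered genes in the first and 3094 and 1942 in the second. Fold changes correlated at r = 0.716 and 0.703. Both treatments were compared with the same untreated libraries, and simulated unchanged groups gave r = 0.500 and 0.501 with no shared calls. The simulation drew genes independently, so it left out shifts of an untreated library that move many genes together. The covariance of the fold changes was 0.558 and 0.477, against 0.0211 and 0.0199 in the simulation, and with 3 untreated libraries the controls could not be split so that each part kept a pair.

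The knockout and both overexpression lines responded to ABA and PEG mostly as wild type did. Of the 13696 genes called for ABA in both the knockout and its wild type, 99.1% changed in the same direction, and of the 20557 called for PEG 99.7% did. In line 1 the shares were 99.8% of 12135 genes for ABA and 99.8% of 25836 for PEG. In line 2 they were 99.9% of 11159 and 99.7% of 25270. These shares count only genes called in both. Of the genes raised and lowered by ABA in wild type, 72.5% and 61.1% were called alike in the knockout. It was 78.9% and 68.8% in line 1, and 73.0% and 63.0% in line 2. For PEG it was 85.2% and 73.3%, 87.2% and 87.8%, and 84.0% and 88.0%, in the same order. Across genes the mutant's and the wild type's changes correlated at r = 0.833 for ABA and 0.915 for PEG in the knockout, at 0.901 and 0.931 in line 1, and at 0.889 and 0.926 in line 2. ABA changed 18374 genes in the knockout, 16053 in line 1 and 14393 in line 2, and PEG changed 24499, 32350 and 30880. ABA-treated wild type replicates 2 and 3 of the overexpression experiment carried genes otherwise seen only in the lines, which limits the ABA values of both lines. These responses were added after the data were examined, and the comparisons of a mutant and its wild type used separate libraries.

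**Figure D1:**
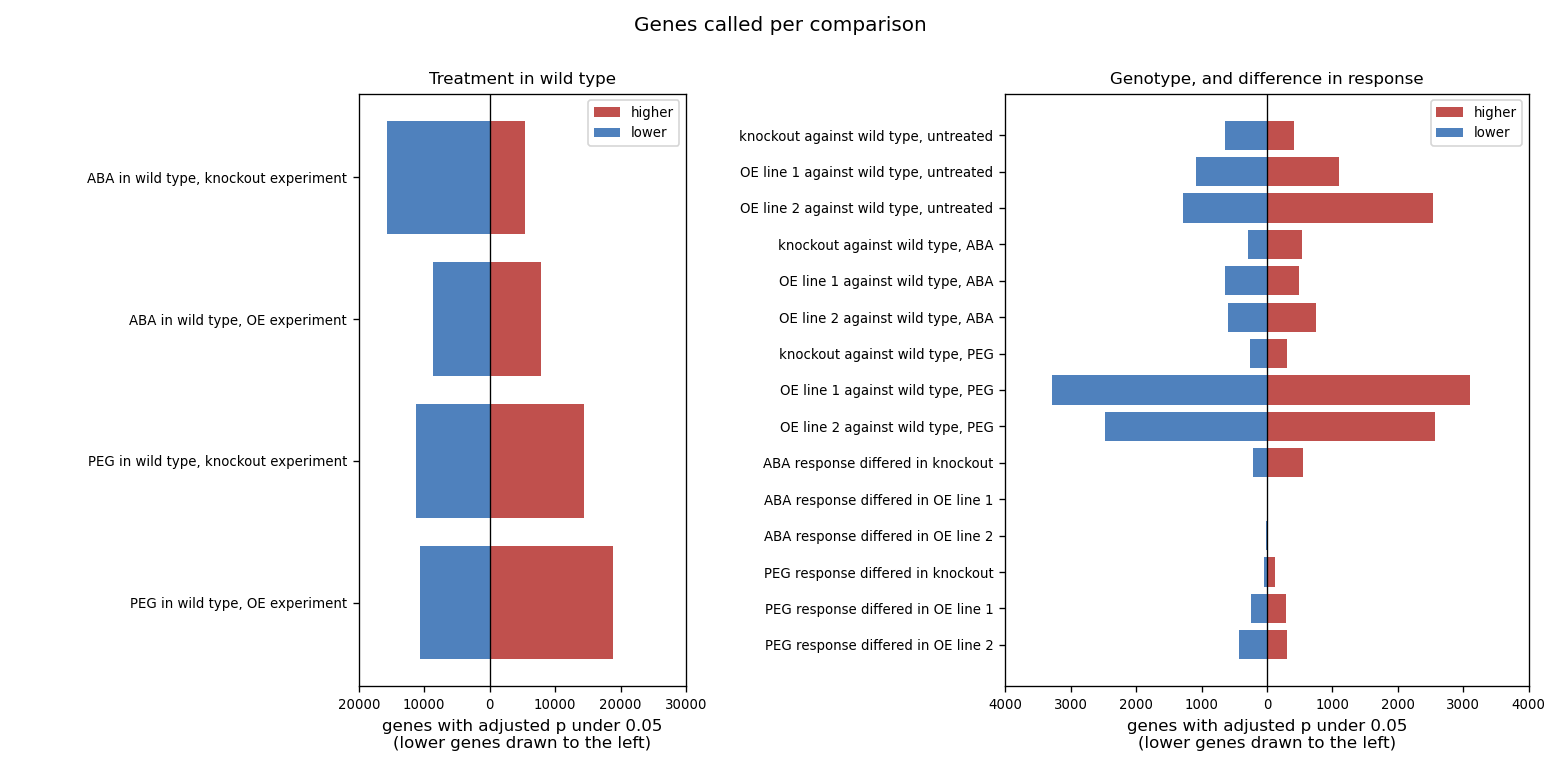
Numbers of genes called (adjusted p under 0.05) in each comparison, with higher genes to the right and lower genes to the left of 0. The left panel shows treatments in wild type, from 16463 to 29501 genes, and the right panel shows genotype comparisons and differences in response, from 10 to 6381 genes.

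The knockout differed from wild type in far fewer genes than either treatment changed. A part of these genes lay side by side on chromosomes C01 and A01. In untreated leaves 1051 genes differed, 412 higher and 639 lower in the knockout. With ABA there were 835, 542 higher and 293 lower, and with PEG 570, 312 higher and 258 lower. On C01, between running numbers 2528 and 2952, 95 of 121 tested genes were called higher by at least 1.5-fold in untreated leaves, 101 with ABA and 102 with PEG, with median log2 changes of 1.56, 1.51 and 1.62. On A01, between 2027 and 2302, 77 of 118 tested genes were called lower in untreated leaves, with a median log2 change of -0.80, and between 2027 and 2298 it was 50 of 117 with ABA and 60 of 117 with PEG (medians -0.62 and -0.75). BnaC01G0259200ZS went from 0.309 ± 0.1202 in untreated wild type to 108 ± 22.6 (SD, n = 3) in the knockout (log2 change 6.36, SE 0.14, limma adjusted p = 1.19e-13), and BnaC01G0259800ZS was listed at 0 in all 3 untreated wild type libraries and at 60.7 ± 2.53 in the knockout. Further along A01, where 12 of 28 tested genes between 4113 and 4213 were called lower, BnaA01G0413200ZS went from 196 ± 4.28 to 0.0437 ± 0.0756 (log2 change -7.56, SE 0.12, limma adjusted p = 1.72e-15). The size of the segment medians depended on the pseudocount and filter, and the untreated C01 median was 3.48 with a pseudocount of 0.1, 2.76 with the stricter filter and 0.27 with no filter.

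Summed over each segment, the C01 genes rose and the A01 genes fell to similar totals in the knockout. In untreated leaves the C01 sum was 384 ± 27.3 in wild type and 1743 ± 113.7 in the knockout (SD, n = 3), with ABA 363 ± 6.17 and 1568 ± 75.1, and with PEG 397 ± 27.3 and 1792 ± 79.1. The A01 sums were 3205 ± 291 and 1651 ± 105 in untreated leaves, 2844 ± 64.7 and 1549 ± 86.0 with ABA, and 3306 ± 124 and 1841 ± 54.3 with PEG. The ratio of the C01 to the A01 sum lay between 0.955 and 1.06 in the 9 knockout libraries and between 0.113 and 0.133 in the 9 wild type libraries. In the overexpression experiment it lay between 0.134 and 0.192 in wild type, 0.156 and 0.180 in line 1, and 0.151 and 0.186 in line 2, over the 49 C01 and 141 A01 genes tested there. The segments were chosen from the same libraries, so the sums describe them and no p-value is given.

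**Figure D2:**
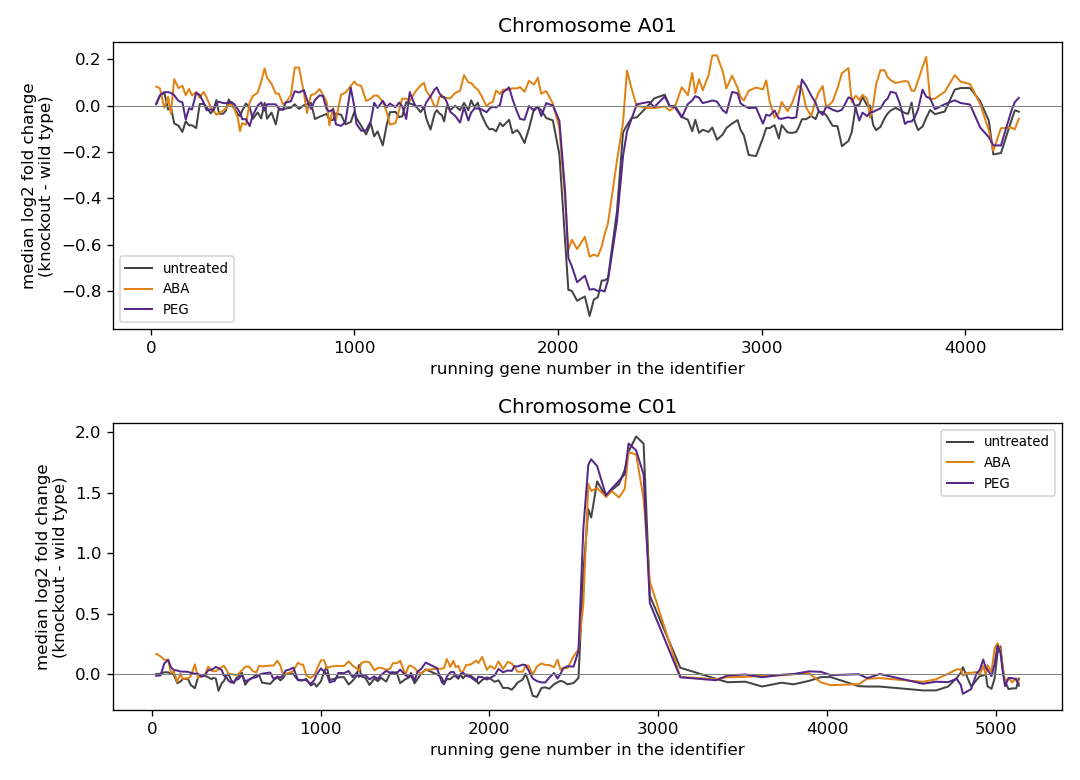
Running median of the log2 fold change (knockout minus wild type) along chromosomes A01 and C01, against the running gene number, for untreated, ABA-treated and PEG-treated leaves. The A01 curves dip between 2027 and 2302 and the C01 curves rise between 2528 and 2952 in all 3 conditions.

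**Figure D3:**
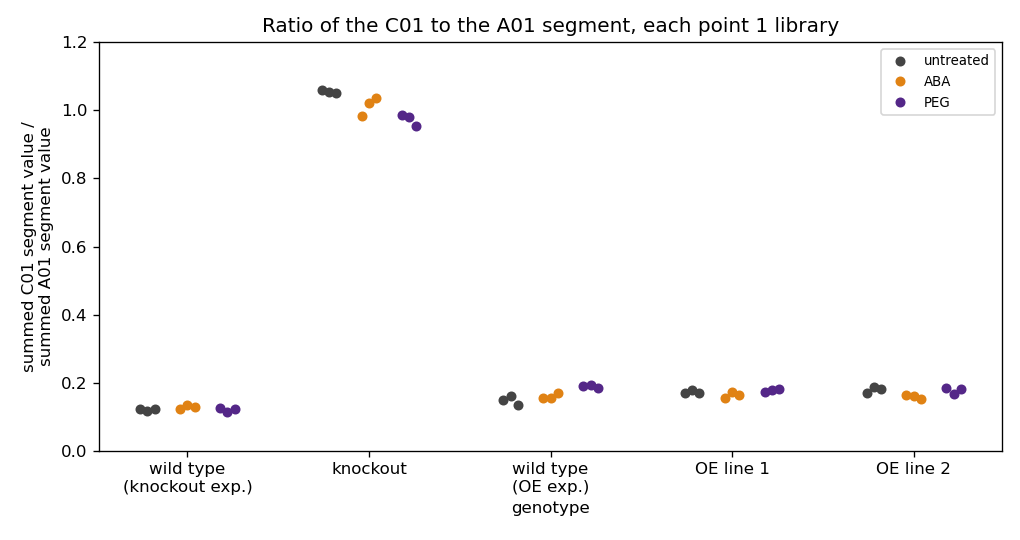
Ratio of the summed C01 segment to the summed A01 segment in each of the 45 libraries, by genotype and condition, where each point is 1 library. The 9 knockout points lie between 0.955 and 1.06, and those of its wild type between 0.113 and 0.133 (121 C01 and 118 A01 genes). Those of the overexpression experiment lie between 0.134 and 0.192, over the 49 C01 and 141 A01 genes tested there. Ratios are therefore not comparable between the experiments.

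In untreated leaves further runs on A09 and C08 were called between knockout and wild type, and there the wild type libraries differed among themselves. On A09 between 7030 and 7207 and on C08 between 5062 and 5298, 28 of 79 and 38 of 97 tested genes were called higher in the knockout. On A09 between 6431 and 6682 and between 6885 and 6983, 43 of 124 and 22 of 56 were called lower. The summed A09 values (7030 to 7207) of untreated wild type replicates 1, 2 and 3 were 290.3, 349 and 24.6, against 543 ± 9.08 (SD, n = 3) in the untreated knockout and 493 ± 23.9 and 536 ± 9.59 in ABA-treated and PEG-treated wild type. The C08 sums of the same replicates were 470.3, 592 and 46.9, against 962 ± 25.8 in the untreated knockout. They were 997 ± 63.6 and 1081 ± 113 in ABA-treated and PEG-treated wild type. Between 6431 and 6682 the A09 sums were 4483 ± 325 in untreated wild type and 3020 ± 261 in the untreated knockout. With ABA and PEG wild type was at 2746 ± 64.9 and 2655 ± 121. These runs set untreated wild type apart from treated wild type too, so the calls do not establish a knockout difference. The ABA and PEG responses of this wild type used the same untreated libraries. Without untreated wild type replicate 3, 1093 genes were called between untreated knockout and wild type. Without that library and PEG-treated knockout replicate 3, a choice made after seeing the data, 1523 were called.

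**Figure D4:**
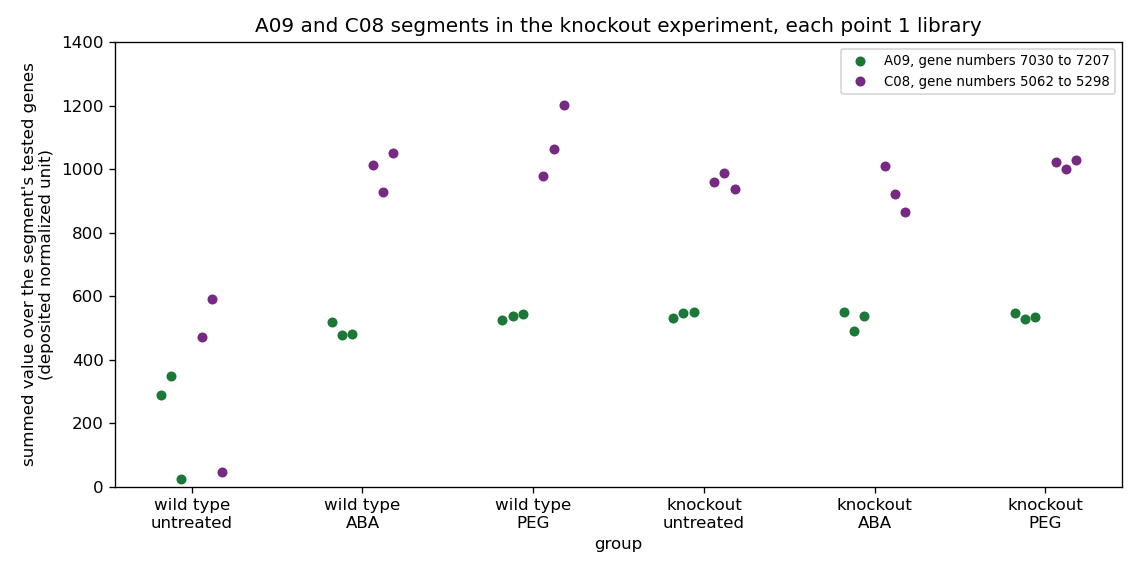
Summed values (deposited normalized unit) of the genes of the A09 segment 7030 to 7207 and the C08 segment 5062 to 5298 in each library of the knockout experiment. Untreated wild type replicate 3 lies at 24.6 and 46.9, and replicates 1 and 2 lie between it and all other groups.

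With segment genes left out fewer knockout differences were called, and the counts changed with the libraries used. The refit left out the segments of all genotype comparisons, those of the lines among them (2404 genes of the knockout experiment). It called 392 genes in untreated leaves, 143 higher and 249 lower, 486 with ABA (316 and 170) and 270 with PEG (146 and 124). Adjusted p-values were recomputed, so the fall is not the number of calls inside segments. The untreated knockout's own segments held 161 higher and 154 lower calls of at least 1.5-fold. Outside segments lay BnaC06G0382800ZS, at 4.95 ± 1.24 in ABA-treated wild type and 892 ± 478 (SD, n = 3) in the ABA-treated knockout (log2 change 7.11, SE 0.47, limma adjusted p = 7.13e-08), and at 5.81 ± 1.00 and 441 ± 210 with PEG. BnaA04G0019800ZS went from 197 ± 90.9 to 8.71 ± 4.42 with ABA (log2 change -4.34, SE 0.44, limma adjusted p = 1.92e-05). The split of the 1051 untreated calls depended on the normalization, with 545 higher and 519 lower after quantile normalization. The untreated count was 564, 601 or 561 without knockout replicate 1, 2 or 3. The ABA count was 552 or 474 without ABA-treated wild type replicate 1 or 3, and 1407 or 465 without ABA-treated knockout replicate 2 or 3. With array quality weights, added after seeing the data, the untreated count was 2095 and the PEG count 9162, in a fit that gave weights of 10.04 and 3.83 to replicate 2 of PEG-treated wild type and knockout.

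Genes were called between both overexpression lines and their wild type in every condition. In untreated leaves 2183 genes differed in line 1, 1099 higher and 1084 lower, and 3826 in line 2, 2542 higher and 1284 lower. With ABA the numbers were 1125 in line 1 (484 higher, 641 lower) and 1355 in line 2 (756 and 599), and with PEG 6381 (3099 and 3282) and 5047 (2570 and 2477). For line 1 with PEG another split of the same libraries, with line 1 replicate 3 grouped with wild type replicates 1 and 2, called 6945 genes. The ABA comparisons rest on a wild type group in which replicates 2 and 3 carried genes otherwise seen only in the lines, at median shares of 0.520 and 0.360 of the lines' level. BnaA04G0023300ZS went from 437 ± 18.2 TPM in untreated wild type to 0.343 ± 0.301 TPM in line 1 and 0.406 ± 0.239 TPM in line 2 (SD, n = 3, log2 changes -8.37 and -8.30, SE 0.24, limma adjusted p = 1.55e-16 and 1.89e-16). BnaC06G0382800ZS went from 0.708 ± 0.431 TPM to 469 ± 11.6 TPM in line 1 and 452 ± 60.3 TPM in line 2 (log2 changes 8.13 and 8.07, SE 1.01), and BnaA10G0187900ZS was listed at 0 in untreated wild type and at 55.5 ± 3.32 TPM and 61.2 ± 4.33 TPM in the lines. The split of line 2 in untreated leaves depended on the normalization, with 2055 higher and 1703 lower after quantile normalization. The untreated count of line 2 was 2186 without its replicate 2. With ABA it was 626 in line 1 and 706 in line 2 without wild type replicate 1, 723 in line 1 without its replicate 2, and 802 or 871 in line 2 without its replicate 1 or 3. With PEG it was 10576 in line 1 and 7734 in line 2 without wild type replicate 3, 2858 and 3086 without wild type replicate 2, 2613 in line 1 without its replicate 2, and 3021 in line 2 without its replicate 1.

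The overexpression lines shared a part of their calls, and nearly all shared calls had the same direction. In untreated leaves 954 genes were higher and 802 lower in both, with ABA 358 and 445, and with PEG 1645 and 1656, while 1 gene was called in opposite directions over the 3 conditions. Independent lists would share 58.8 higher and 29.3 lower genes in untreated leaves, 7.71 and 8.09 with ABA, and 168 and 171 with PEG. Fold changes of the lines correlated at r = 0.855, 0.798 and 0.837. Simulated unchanged groups compared with a common simulated wild type group gave 0.501, 0.501 and 0.499 and no shared calls. Genes were drawn independently there, so the simulation could not show shared calls from a wild type library that shifts many genes together. The covariance was 0.138, 0.0834 and 0.178 against 0.0199, 0.0199 and 0.0198 in the simulation. Each line had 3 wild type libraries in common with the other, too few to split, so part of the excess may come from these shared libraries. The lines also had chromosome segments in common, such as on A04. In a refit without the genes of all segments, 1077, 360 and 2465 genes were shared in the same direction (untreated, ABA, PEG). With all genes it was 1756, 803 and 3301. The agreement therefore does not separate overexpression from these segments.

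Calls in the overexpression lines were also gathered in chromosome segments. On A04, between 378 and 752, 79 of 203 tested genes were called lower by at least 1.5-fold in PEG-treated line 1 and 78 in line 2, with median log2 changes of -0.40 and -0.42. The summed A04 value was 3540.3 ± 86.3 TPM in untreated wild type, 2147 ± 70.4 TPM in line 1 and 2168 ± 28.2 TPM in line 2 (SD, n = 3). On A02, between 4020 and 4198, 35 of 84 genes were called higher in each line with PEG, with median log2 changes of 0.47 and 0.55. On A01, between 3694 and 3789, 21 of 52 were called lower in line 1 with PEG, and between 3657 and 3795 31 of 80 in line 2. Segments held 13.8% of the higher and 20.9% of the lower calls of at least 1.5-fold in untreated line 1, 11.2% and 16.8% in line 2, and 46.0% and 29.2% in the untreated knockout. In a refit without the segments of all genotype comparisons (2188 genes) the untreated counts were 1375 in line 1 and 2861 in line 2. The ABA counts were 501 and 790, and these falls too are not the numbers of calls inside segments.

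Knockout and overexpression changed few genes in common, and with ABA and PEG more of these moved in the same than in opposite directions. In untreated leaves 53 genes moved in opposite directions in the knockout and both lines, 13 of them higher and 40 lower in the knockout, where 4.67 and 11.3 would be expected (Fisher's exact p = 0.000945 and 7.64e-12). Another 51 moved in the same direction, 27 higher and 24 lower, where 5.37 and 9.82 would be expected (Fisher's exact p = 8.61e-12 and 6.60e-05). With ABA 16 genes were opposite (11 higher and 5 lower in the knockout, where 3.74 and 2.01 would be expected, Fisher's exact p = 0.00150 and 0.0523) and 80 alike (49 higher and 31 lower, where 2.97 and 2.53 would be expected, Fisher's exact p = 1.80e-44 and 2.46e-24). With PEG 22 were opposite (11 and 11, where 7.61 and 7.91 would be expected, Fisher's exact p = 0.194 and 0.271) and 112 alike (67 and 45, where 6.92 and 8.70 would be expected, Fisher's exact p = 5.44e-47 and 9.59e-20). BnaA02G0407700ZS was at 15.4 ± 9.54 in untreated wild type and listed at 0 in the knockout, while it was listed at 0 in the wild type of the overexpression experiment and at 39.6 ± 5.94 TPM and 39.1 ± 4.64 TPM in the lines (SD, n = 3). BnaA04G0058400ZS was higher in the knockout (log2 change 2.01, SE 0.28) and lower in both lines (-3.62 and -3.49, SE 0.18). Both genes lie inside segments of the lines, the first in the raised A02 segment and the second in the lowered A04 segment. Fold changes of the knockout and the mean of both lines correlated across genes at r = -0.04 in untreated leaves, 0.0879 with ABA and -0.0575 with PEG (Spearman -0.0977, -0.00168 and -0.167). Overlaps in the same and in opposite directions both exceeded the expected numbers in every condition, and neighbouring genes in segments were called together. Fisher's exact test takes genes as independent, so the p-values above do not measure a shared effect. The ABA counts also rest on wild type replicates 2 and 3 of the overexpression experiment, which carried the lines' marker genes. The near tie in untreated leaves depended on the libraries and segments. Without the libraries that stand apart, 51 were opposite and 101 alike in untreated leaves. With segment genes left out, 10, 5 and 10 genes were opposite and 26, 52 and 74 alike in untreated, ABA-treated and PEG-treated leaves.

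The response to ABA differed between the knockout and wild type in 769 genes, 555 with a higher and 214 with a lower change in the knockout (interaction, limma, adjusted p under 0.05). The response to PEG differed in 171 genes, 124 higher and 47 lower. The split of the ABA genes depended on the normalization, with 412 higher and 292 lower after quantile normalization. On A09, 11 of 30 tested genes between 6516 and 6581 and 11 of 27 between 6946 and 6983 were among the higher ABA genes, inside the region in which untreated wild type libraries differed. The ABA count was 1443 without ABA-treated knockout replicate 2, and without another single library it was 419 or 501 (untreated wild type replicate 1 or 2), 390, 330 or 329 (ABA-treated wild type replicate 1, 2 or 3), 378, 459 or 353 (untreated knockout replicate 1, 2 or 3), and 484 or 317 (ABA-treated knockout replicate 1 or 3). The PEG count was 85 or 113 without PEG-treated wild type replicate 2 or 3, 83, 94 or 108 without untreated knockout replicate 1, 2 or 3, and 89 without PEG-treated knockout replicate 2.

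In the overexpression lines fewer genes were called for a different response to ABA than to PEG. For ABA 10 genes were called in line 1, 4 higher and 6 lower, and 15 in line 2, 4 higher and 11 lower. For PEG 535 genes were called in line 1, 292 higher and 243 lower, and 730 in line 2, 306 higher and 424 lower. In ABA-treated wild type replicates 2 and 3 genes otherwise seen only in the lines stood at 0.520 and 0.360 of the lines' level, which limits the ABA counts. After quantile normalization the split of line 2 with PEG was 441 higher and 378 lower. The ABA counts rested on the wild type libraries, and were 180 and 185 without ABA-treated wild type replicate 1, 17 and 23 without untreated wild type replicate 2, 22 in line 1 without ABA-treated wild type replicate 2 alone, and 28 in line 2 without its replicate 3 alone. They were 19 or 6 without ABA-treated line 1 replicate 1 or 2, 5 or 63 without untreated line 2 replicate 2 or 3, and 9 without ABA-treated line 2 replicate 3. For PEG they were 3713 in line 1 and 1747 in line 2 without PEG-treated wild type replicate 3, and 192 and 450 without its replicate 2. For line 1 they were 248 without PEG-treated wild type replicate 1, 346, 220 or 348 without untreated wild type replicate 1, 2 or 3, 284, 190 or 236 without untreated line 1 replicate 1, 2 or 3, and 180 or 1678 without PEG-treated line 1 replicate 2 or 3. For line 2 they were 389 without untreated wild type replicate 2, 354 without its own untreated replicate 2, and 344 or 436 without its PEG-treated replicate 1 or 2.

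Genes that PEG or ABA changed in the other experiment's wild type were counted in each genotype comparison, and no set passed the stricter tests. Of 3958 genes raised by PEG there, 874 were called higher and 140 lower in PEG-treated line 1 (median log2 change 0.22), and 634 and 122 in line 2 (0.19). Of 4306 lowered genes, 156 were called higher and 749 lower in line 1 (median -0.22), and 179 and 635 in line 2 (-0.19). Untreated line 2 already lay the same way, with 516 raised genes called higher and 83 lower (median 0.16) and 175 lowered genes called higher and 300 lower (-0.10). In untreated line 1 the numbers were 180 and 80 (0.05), and 115 and 186 (-0.08). For the difference in PEG response, 92 raised genes were called higher and 30 lower in line 1, and 71 and 58 in line 2. The median difference over all 3958 raised genes was 0.16 in line 1 and -0.01 in line 2. In the PEG-treated knockout, 16 of 5358 raised genes were called higher and 76 lower (median -0.13), and 24 of 3621 lowered genes were called higher and 11 lower (0.13). With the preset correlation camera gave adjusted p = 3.29e-10 and 6.15e-08 for the raised genes in PEG-treated lines 1 and 2, 1.98e-05 in untreated line 2, and 1.05e-07 in the PEG-treated knockout. With an estimated correlation the adjusted p was 0.762 for each of these, and with fry it was 0.0887, 0.133, 0.133 and 0.538. Of 2236 genes raised by ABA there, 591 were called higher and 98 lower in PEG-treated line 1 (median 0.28). In PEG-treated line 2 it was 424 and 70 (0.24). For these, camera gave adjusted p = 2.39e-10 and 1.74e-09 with the preset correlation and 0.762 for both with the estimated one. With fry it was 0.0664 for both, so no shift of any of these sets is established.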

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

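For the splits in this part the bound was written down after the real counts were known and before the splits were run, and those with the genotype effect removed were chosen after the first splits had been seen. A difference between groups brought forward the 6 interactions, in each of which limma called some genes for a different treatment response in a mutant than in wild type. In the knockout this held for 769 genes with ABA (555 with a higher and 214 with a lower change) and 171 genes with PEG (124 and 47). In line 1 it held for 10 genes with ABA (4 and 6) and 535 with PEG (292 and 243), and in line 2 for 15 genes with ABA (4 and 11) and 730 with PEG (306 and 424). The calls for ABA in the lines rest in part on wild type replicates 2 and 3, which carried the lines' marker genes at 0.520 and 0.360 of the lines' level. Such libraries shrink the genotype difference under ABA and can produce a false interaction, so a different response to ABA in the lines is not established. Under an unadjusted p of 0.05, limma called 7253 and 4332 genes in the knockout, 2837 and 8593 in line 1, and 3001 and 6809 in line 2.

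Each interaction was set against 100 splits of the same libraries into equal parts within each treatment, the real one and 99 drawn at random. For the knockout with ABA 1 split, the real one, called as many genes, and the highest other split called 148. For the knockout with PEG 4 splits did, with 872 in the highest other split. Both met the bound of 5 in 100, but with no correction for the number of interactions tested. Chance is therefore not excluded for either. Both knockout interactions also use the untreated wild type libraries, which differed among themselves on A09 and C08. Splits cannot tell such a difference between samples from a different response. With segments left out the counts were 581 with ABA and 87 with PEG. For the overexpression lines the splits cannot tell. With ABA 13 splits in line 1 and 17 in line 2 called as many genes as the real 10 and 15, with highest others of 1432 and 2822. With PEG 17 splits in line 1 and 11 in line 2 called as many as the real 535 and 730, with highest others of 5714 and 3026. Splits that kept the genotypes apart in 1 treatment and mixed or exchanged them in the other turned the genotype difference into a false interaction. With ABA all of the other splits that reached the real count were of this kind (12 and 16), and so were those for the knockout with PEG (3) and line 2 with PEG (10). For line 1 with PEG it was 8, and 8 more mixed the genotypes in both treatments and called up to 2447 genes, several times the real count, which points to a structure of the samples besides genotype in that comparison.

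The splits were therefore repeated with the genotype effect common to both treatments removed from each gene. For the knockout 1 split, the real one, called as many genes with ABA (768, highest other 6) and 1 with PEG (171, highest other 5). In line 1 with ABA 1 split, the real one, called as many (10, highest other 6), and in line 2 1 with ABA (20, highest other 7) and 1 with PEG (729, highest other 147). For the knockout this repeat adds no support to the first splits. For ABA in both lines and PEG in line 2 chance is not excluded by it, although the bound was met. In each case the removed effect was estimated under the real grouping. The removal therefore left the real interaction in place and took noise between the genotypes out of the other splits only. For line 1 with PEG 8 splits called as many as the real 538, with 2865 in the highest other, so chance or a structure of the samples remains possible there. No biological explanation of the interactions was tested.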

How the results depend on the processing

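All sets of calls kept genes in both directions where any were left, and the counts moved with the settings as follows; the cause was not tested unless stated. A required 2-fold change moved 27 of 30 counts, by its construction: ABA in wild type 6227 and 4523, PEG 9072 and 10017; knockout untreated, ABA and PEG 393, 369 and 338; line 1 938, 523 and 1670; line 2 1225, 569 and 1502; interactions of the knockout with ABA 490, line 1 with PEG 339 and line 2 with PEG 440; agreement of the lines 790, 387 and 1063 and of the wild types 2155 and 4940; opposite changes 24, 7 and 9; same-direction changes 21, 42 and 71. Array quality weights moved 10 of 19: knockout untreated 2095 and PEG 9162, line 1 untreated 4323 and ABA 2024, line 2 ABA 2531, interactions of the knockout 1746 and 2874, of the lines with ABA 177 and 97, and of line 1 with PEG 1164. A filter of at least 5 in 3 libraries moved 6, with fewer genes tested: 11546 and 14935 for ABA and PEG in the knockout experiment's wild type, 597, 537 and 297 for the knockout, and 107 for its PEG interaction. With only the compared groups in the fit, and so fewer samples, 13 moved: knockout 433, 455 and 310, line 1 ABA 225 and PEG 1030, line 2 1527, 346 and 1742, ABA interactions 4 and 0 (for the latter limma called 3121 genes at an unadjusted p under 0.05), PEG interactions 61, 95 and 196. The ABA interactions of the lines were 19 and 24 with no filter, 16 and 28 with no mean trend, and that of line 1 was 16 with a pseudocount of 0.1 and 22 after quantile normalization. The pseudocount of 0.1 gave 108 and 331 for the PEG interactions of the knockout and line 1. With line 1 alone 46 changes were opposite with PEG, and with line 2 alone 78 were alike in untreated leaves. With segments left out (2404 and 2188 genes) 16 of 24 moved: knockout 392, 486 and 270, line 1 1375 and 501, line 2 ABA 790, interactions of line 2 with ABA 8 and of the knockout with PEG 87, agreement of the lines 1077 and 360, opposite 10, 5 and 10, same-direction 26, 52 and 74. Without the libraries that stand apart, which leaves 1 ABA-treated wild type library assumed to vary like other groups, 7 of 30 moved: ABA in the overexpression experiment's wild type 10435, knockout interactions 1420 and 293, ABA interactions of the lines 22 and 25, opposite PEG changes 13, same-direction untreated changes 101. Rescaling to equal library sums and using the first transcript only moved none of 7 and 12 counts.

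Leaving out single libraries gave 18044 to 18957 and 13125 to 15775 for ABA in the wild types, 23077 to 24558 and 25558 to 28769 for PEG, 561 to 1093, 465 to 1407 and 417 to 682 for the knockout, 1489 to 1896, 626 to 1106 and 2613 to 10576 for line 1, and 2186 to 4135, 706 to 1402 and 3021 to 7734 for line 2, in the order untreated, ABA, PEG. Interactions gave 317 to 1443, 6 to 180 and 5 to 185 with ABA and 83 to 245, 180 to 3713 and 344 to 1747 with PEG. The samples share only a replicate number, and at most 2 of 3 samples correlated best with their own number. The replicate block moved the PEG interaction of line 1 from 535 to 355 and no other count by more than 1.5 times. Of 1433 values of named genes under all settings, 1406 kept direction and side of the threshold, 27 kept direction only and 0 reversed. These values repeat 88 results of a gene in a comparison. The genes were chosen by their calls in the same data, which favours such stability. Of 96 segment medians 16 moved and 0 reversed. The variants set out beforehand for the gene lists (estimated correlation, fry) and for the target gene without scaling were not run, because identifiers were not matched to names. Read depth is unknown, so genes at low values may differ without being called.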

Other observations

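The observations in this paragraph were made after the results were seen. Near the start of A08, line 1 had lower values than wild type, with a wide spread between its libraries, and no such segment was found in line 2. In line 1 between running numbers 2 and 126, 53 of 78 tested genes were called lower with ABA (median log2 change -1.05) and 35 with PEG (-0.69). The summed values of line 1 were 1424, 1208 and 965 TPM in the untreated replicates 1, 2 and 3, 605, 731 and 1133 TPM with ABA, and 1161, 698 and 2069 TPM with PEG. Wild type lay at 2032 ± 79.2, 2191 ± 133 and 2049 ± 75.1 TPM (SD, n = 3) and line 2 at 1888 ± 128, 2147 ± 82.1 and 2200.2 ± 43.7 TPM.

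In the knockout 216 genes differed from wild type in all 3 conditions, 143 higher and 73 lower, and 157 of them (72.7%) lay in chromosome segments. In line 1 there were 661 with 50.8% in segments, in line 2 788 with 45.7%, and in both lines 570, 234 higher and 336 lower, with 53.7%. The segments were defined from calls in these same comparisons, so genes called repeatedly fall in them partly by construction. Outside segments, BnaC06G0382800ZS was far higher in untreated leaves of the knockout (1105 ± 198, wild type 37.9 ± 28.7) and of both lines (469 ± 11.6 and 452 ± 60.3 TPM, wild type 0.708 ± 0.431 TPM; SD, n = 3). In ABA-treated wild type replicates 1, 2 and 3 of the overexpression experiment this gene was at 1.196, 258 and 199 TPM.

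For the A01 and C01 segments of the knockout, the segments and all 3 tests were chosen after the calls were seen, and for the shuffles alone the bound was written down before they were run. An exchange that leaves the knockout with more C01 and fewer A01 copies than wild type fits. The summed level of both segments in the knockout was 0.946 of wild type in the condition farthest from 1. This does not establish an exchange, because the segments were chosen from the same libraries and no table pairs their genes as copies. Nor does the sum tell whether the knockout or its wild type would carry it. A response scattered over the genome is excluded as the source, as 0 of 100 shuffles of gene order gave such a run. The median log2 change outside segments was -0.0502 in the condition farthest from 0. Because the values were already normalized, this median could not decide whether scaling played a part. A common factor per library could not raise C01 and lower A01 in the same libraries, so such a factor is not the source. Whether loss of BnNAC038 itself changes these segments stays open, because there is 1 knockout line.

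For the A09 and C08 segments of untreated wild type in the knockout experiment, all tests were chosen after the results were seen. Knockout plants in wild type replicates 1 and 2 are excluded by their C01 to A01 ratio of at most 0.123, and loss of reads by the 0.0468% of genes outside segments (7 of 14951) that were absent there while present in replicates 1 and 2, against 14 of 29 in the segments. Copy differences of these segments among plants fit, since the positions of replicates 1 and 2 between the knockout level and replicate 3 differed by at most 0.0824 between lowered and raised segments. No biological explanation from the design was tested.

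For ABA-treated wild type replicates 2 and 3 of the overexpression experiment, all tests were chosen after the results were seen. Genes otherwise seen only in the overexpression lines (9 genes) stood at a median share of 0.520 and 0.360 of the lines' level, and genes absent from the lines (11 genes) at 0.516 and 0.695 of their level in replicate 1. A mixture with plants or RNA of the lines' genotype fits, since the shares summed to 1.06 in the replicate farther from 1. A swap with an ABA-treated overexpression library is excluded, as all 6 had wild type markers at 0. A response of the markers to ABA was not seen in replicate 1, which had line markers at 0, but 1 library does not exclude it. Results that use these libraries are bounded by this, and no biological explanation from the design was tested.

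For the splits in this paragraph the bound was written down after the real counts were known and before the splits were run. Each comparison of a pair of groups had 10 splits of its libraries, too few to exclude chance. The real split called the most genes, with a count of 1, in all but line 1 with PEG. The real and highest other values were 21185 and 0 (ABA, wild type of the knockout experiment), 16463 and 1 (ABA, wild type of the overexpression experiment), 25633 and 1 and 29501 and 3 (PEG, the same wild types), 1051 and 6, 835 and 14, and 570 and 3 (knockout untreated, ABA, PEG), 2183 and 0 and 1125 and 1 (line 1 untreated, ABA), and 3826 and 17, 1355 and 1, and 5047 and 23 (line 2 untreated, ABA, PEG). For line 1 with PEG 2 splits called as many as the real 6381, the other calling 6945 with line 1 replicate 3 grouped with wild type replicates 1 and 2, and the next 587. The summed A04 level of wild type replicate 3 (3429 TPM) and line 1 replicate 3 (2063 TPM) was that of their own genotype. On A08, however, line 1 replicate 3 was at 2069 TPM, near PEG-treated wild type (2049 ± 75.1 TPM, SD, n = 3). The lowest PEG-treated line 1 library was at 698 TPM there. The A08 segment therefore did not separate line 1 replicate 3 from wild type.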
